A study of Mus musculus with 4 samples.

How the data were processed

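Single-cell RNA profiles of sorted tumour myeloid cells from mice were measured with 10x Genomics 3' chemistry in 4 libraries, 1 per group. Per the labels, 3 libraries came from spontaneous mammary tumours of 1 pool of 4 mice, and 1 library came from tumours grown in a pool of 5 mice after 200000 cultured tumour cells were injected into the mammary fat pad. The deposited values were raw UMI counts per gene and barcode for 31053 genes and 737280 barcodes per library, with empty droplets included. Per the submitters' processing notes, the counts were made with Cell Ranger 3.0.2 on the mouse build mm10. Per the labels' protocols, the sort kept CD45+ cells negative for CD90.2, B220, NK1.1 and Ly6G and positive for CD11b or CD11c, so T cells, B cells, NK cells and neutrophils were gated against. Gene positions were taken from a GENCODE annotation of GRCm38, the assembly that mm10 names, by matching the Ensembl identifiers in the files (31011 of 31053, 99.9%).

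Barcodes were called as cells per library when their UMIs reached 0.1 of the 99th percentile of the top 3000 barcodes, with at least 300 genes and at most 10% mitochondrial UMIs. This left 14226 cells. Scrublet, as run in scanpy, called 1 of 14561 barcodes a doublet where 466 were expected at 0.8% per 1000 barcodes, so the caller did not work and doublets remain among the cells. The 4 libraries were clustered together on log counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, without integration. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.

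The marker lists of 16 cell types, the 18 gene lists, the rule for named genes and most other settings were fixed before the data were examined. The scoring rule that turned markers into names was set after the clusters were seen. Each marker was placed between its lowest and highest cluster on log2(CPM + 5), and classes with at least 3 markers at a level of 0.5 or more were ranked by their mean level. Markers that reached 20 CPM in no cluster were left out, and red cells needed 10% haemoglobin UMIs. A name was refused when another class had more markers than its own among the cluster's 10 highest folds, taken over genes with at least 50 CPM. A class ranked lower needed 1 marker of its own there, and so did a cluster whose median UMIs were under 1/3 of those of its own libraries. Lists of 2 further lineages, pigment cells and skeletal muscle, were added after the clusters were seen. Of 26 clusters 22 were named, holding 94.6% of the cells, and 10 were macrophage-like.

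UMIs were summed over the cells of a class in each library and given as CPM (UMIs of a gene scaled to a library total of 1e6), with log2 ratios for genes at 10 CPM or more in the higher library and a floor of 3 UMIs per library. With 1 library per group there was no test, so no p-value, standard error or count of changed genes is given. The 95% intervals were exact Poisson for a CPM, exact conditional binomial for a fold and exact Clopper-Pearson for a share, and they cover counting error only. The difference of 2 shares took its interval from the bounds of both, and a list's median took its interval from 1000 Poisson draws. The median of a list was also placed among 10000 random lists of the same size, drawn from the 200 genes nearest in mean expression, as a description of these libraries. Named genes were those of the sort, the 12 highest and 12 lowest ratios at 100 CPM or more without mitochondrial genes and symbols of the Gm and Rik type, and up to 4 members per list with the largest ratios at 50 CPM or more. In other classes with at least 50 cells in both libraries, the 5 highest and 5 lowest genes were taken. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, with 0 cells left out.

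The calculation of ratios and intervals was checked on simulated sums over all called cells, with 200 changed genes and counting error only. Such draws follow the same model as the intervals, so coverage near 95% was built in. All other simulated genes were unchanged, whereas in the data more genes differed. The check therefore covers the calculation and says nothing of the spread between libraries. For the CD11b-hi and CD11b-lo sums (6953 genes), 95.1% of intervals covered the true fold, and the median error was 0.03 at 1 log2 unit and 0.04 at 2 log2 units. For the orthotopic and spontaneous sums (7325 genes), the coverage was 95.2%, with median errors of 0.04 and 0.05. Of 1000 unchanged lists of 12 genes, 4.0% and 4.1% fell outside the central 95% of random lists. Free RNA was profiled in barcodes with 10 to 100 UMIs. Its share in macrophage-like cells was estimated from epithelial, B cell, fibroblast, endothelial and pigment-lineage genes. It was 7.13% in the spontaneous total sort, 9.18% in CD11b-hi, 4.65% in CD11b-lo and 13.9% in the orthotopic library. Some of these cell types were present in the libraries. Remaining doublets with them, or expression of these genes by macrophages, would raise the estimate.

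The values were recomputed with at least 1000 or 500 UMIs per barcode, at most 5% mitochondrial UMIs, called doublets kept, Leiden resolution 0.5 or 2.0, each library clustered on its own, free RNA subtracted, the mean of each cell's CPM, median-of-ratios scaling, no CPM minimum or 50 CPM, cycling clusters left out (cell cycle genes at 4 times the median cluster or more), all called cells, and the ductal list without Itgax. Chosen after seeing the data were the removal of the highest doublet scores, macrophage markers without Apoe, and counting in the unnamed clusters nearest to macrophages. The orthotopic and spontaneous libraries differ in tumour model, pool and library at once, so these cannot be separated.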

Results

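Myeloid cells of mouse mammary tumours were profiled in 4 single-cell libraries. The spontaneous tumours arose in MMTV-PyMT mice, in which a viral oncogene is expressed in mammary epithelium, and were sorted as total myeloid cells, as a CD11b-hi fraction and as a CD11b-lo fraction. The orthotopic tumours grew from injected cells and were sorted as total myeloid cells. The files held 26510307 UMIs for the spontaneous total sort, 38943049 for CD11b-hi, 66878706 for CD11b-lo and 68138944 for the orthotopic library. Called cells numbered 2040, 2982, 4862 and 4342, with median depths of 8943, 9470, 10517.5 and 10122.5 UMIs. There were no replicates, and all intervals cover counting error only. The series title names macrophage heterogeneity and tumour niches as its subject.

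Macrophage-like cells formed 65.0% of the CD11b-hi cells (95% interval 63.2 to 66.7) and 88.2% of the CD11b-lo cells (87.3 to 89.1). Classical monocyte-like cells, the blood-derived precursors of many tissue macrophages, formed 16.4% and 1.01%. The CD11b-hi share of this class was 0.436% at Leiden resolution 0.5, 0.481% with the highest doublet scores removed, 8.42% at resolution 2.0 and 9.40% at 5% mitochondrial UMIs. Type 1 conventional dendritic cells (cDC1), which present antigen to CD8 T cells, formed 2.18% of CD11b-lo cells and 0 of 2982 CD11b-hi cells. The limit used for a count of 0 was 0.101% (3 cells of the total), and the exact 95% interval reached 0.124%. The fractions were defined by sorting on CD11b. The difference in macrophage-like share was -23.2 percentage points (-25.2 to -21.2). It was -7.99 at Leiden resolution 0.5, -10.7 with the highest doublet scores removed, -12.2 with the unnamed clusters nearest to macrophages counted in, and -15.3 with each library clustered on its own. Unnamed clusters held 7.99% of the spontaneous total sort, 12.3% of CD11b-hi, 1.38% of CD11b-lo and 3.92% of orthotopic cells.

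**Figure D1:**
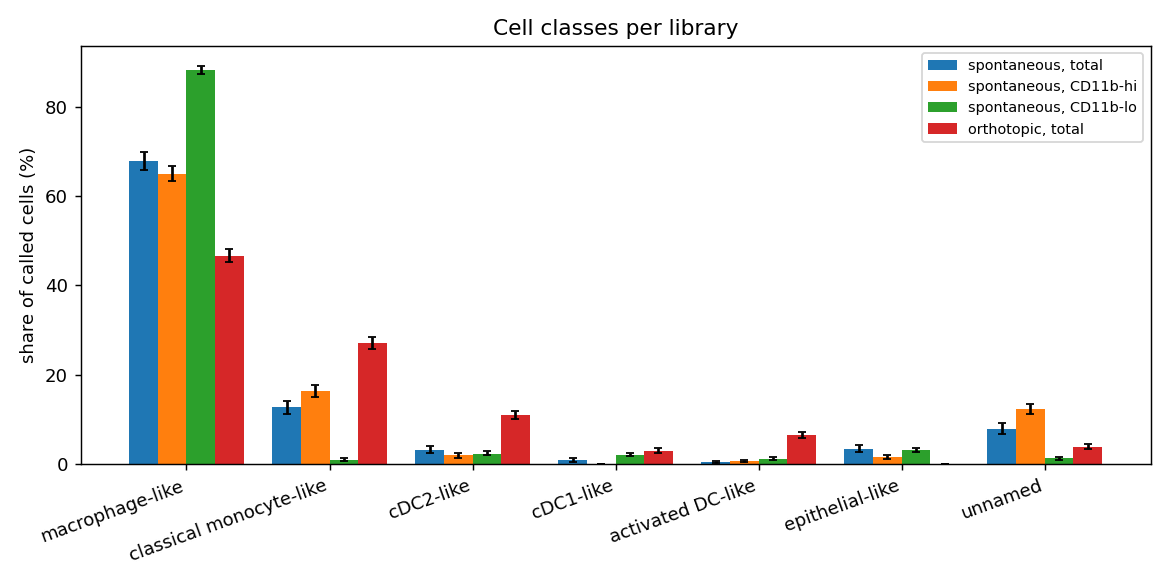
Share of called cells in each class (percent, y axis) for the 4 libraries, with exact 95% binomial intervals that cover counting error only. Macrophage-like cells form 88.2% of CD11b-lo cells and 46.7% of orthotopic cells.

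Within macrophage-like cells, the CD11b-hi library was higher in genes of stromal tissue macrophages and of alternative activation, and lower in MHC class II genes. Itgam, which encodes CD11b itself, was 7.58-fold higher (7.11 to 8.08), and Itgax, which encodes CD11c, stood at 157 CPM against 252 CPM. F13a1, the A subunit of coagulation factor XIII, was 114-fold higher (87.8 to 150). Folr2, a folate receptor of tissue-resident macrophages, was 22.4-fold higher (20.4 to 24.7), and Spp1, the secreted matrix protein osteopontin, stood at 4868 CPM against 608 CPM. Dnase1l3, a secreted DNase, was 8.23-fold lower (7.43 to 9.13), and Cd74, the invariant chain of MHC class II, was 2.33-fold lower.

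Retnla, a secreted protein of alternatively activated macrophages, had the highest ratio, at 928 CPM against 2.28 CPM. Retnla was more abundant in the free RNA of the CD11b-hi library (4240.5 CPM) than in its macrophage-like cells, and so was the chemokine gene Ccl8 (2999 CPM against 908 CPM). After thinning, a Retnla UMI was found in 18.9% of CD11b-hi macrophage-like cells, 37.7% of B cell-like cells and 11.9% of cDC2-like cells. For Ccl8 these shares were 23.7%, 42.6% and 6.78%. C1qa, a macrophage gene, was found in 83.6% of these B cell-like cells and 25.4% of the cDC2-like cells, so the B cell-like class was a poor reference for free RNA. The Ccl8 share (21.9 to 25.7) lay above that of cDC2-like cells (1.88 to 16.5), whereas for Retnla the intervals overlapped (17.2 to 20.8 against 4.91 to 22.9). The level of Retnla in these cDC2-like cells was 112 CPM (86.3 to 142), below the 928 CPM of macrophage-like cells, so free RNA at that level would not supply most of it. The free RNA share of 9.18% estimated for the macrophage-like cells allows a larger part than that level. Of 117566 Retnla UMIs in all called CD11b-hi cells, 20763 lay in macrophage-like cells. For Folr2 the share was 15.8% (14.2 to 17.5) in CD11b-hi against 0.58% in CD11b-lo macrophage-like cells, beside 9.84% (3.70 to 20.2) of CD11b-hi B cell-like cells and 1.69% of cDC2-like cells. Without thinning, the Folr2 shares were 48.2% and 4.43%, and those of Retnla and Ccl8 in CD11b-hi were 74.0% and 62.0%. Median depths in CD11b-hi were 10046 UMIs for macrophage-like, 11174 for B cell-like and 9578 for cDC2-like cells.

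Of 14 measured genes of the stromal list, 11 were at least 1 log2 unit higher in CD11b-hi and 0 were lower, with a median of 3.72 (3.65 to 3.77) above all 10000 random lists. Cbr2, a carbonyl reductase, was 25.7-fold higher, and Gas6, a ligand that bridges dying cells to phagocytes, was 6.37-fold higher. Of 12 genes of the ductal list, 3 were lower and 0 higher, with a median of -0.74 (-0.78 to -0.73) below all random lists. These 3 were the collagenase gene Mmp13 (2.73-fold lower) and the adhesion genes Cadm1 (2.32-fold lower) and Vcam1 (2.19-fold lower). In the lipid-associated list 7 of 15 were higher, among them Gpnmb (8.62-fold) and the fatty acid binding protein gene Fabp5 (4.19-fold), and the median was 0.91. In the MHC class II list 3 of 9 were lower, with a median of -0.96, and H2-Ab1 fell from 18807 CPM in CD11b-lo to 9100 CPM. Most CD11b-hi macrophage-like cells lay in clusters 11 (37.0%) and 12 (30.8%), and most CD11b-lo cells in clusters 0 (30.4%) and 2 (25.6%).

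The alternative activation list had 6 of 10 genes higher (median 2.31), among them Arg1, which degrades arginine, at 34.6-fold, and the lectin gene Clec10a at 15.3-fold. In the monocyte-derived list 7 of 8 were higher (3.37), with S100a4 at 8.80-fold. The complement list had 5 of 10 higher (1.05), led by C4b at 20.5-fold. Chemokine genes had 5 of 11 higher and 1 lower (0.92), with Ccl2 5.23-fold higher and Ccl5 at 109 CPM against 273 CPM. Inflammatory cytokine genes had 6 of 12 higher (0.95), with the neutrophil attractant gene Cxcl1 at 3.75-fold. Efferocytosis genes had 5 of 10 higher (0.84), hypoxia and glycolysis genes 5 of 14 (0.87), and dissociation response genes 4 of 17 (0.55). Matrix remodelling genes had 6 of 14 higher and 2 lower (0.43), with the fibronectin gene Fn1 26.3-fold higher. No member was at least 1 log2 unit apart in the MHC class I (-0.08), interferon response (0.36), S phase (0.11) and G2 and M phase (0.11) lists. Among markers of other cells, the median was 3.59 for classical monocytes and -2.43 for red cells, whose genes were lower in 4 of 4 cases, against 0.003 for the macrophage markers. It was 3.94 for cDC2, 1.41 for non-classical monocytes, -0.38 for cDC1, 0.23 for plasmacytoid dendritic cells and -0.27 for neutrophils, each from 3 to 5 measured genes. For the red cell gene Hbb-bs, at 40.8 CPM in CD11b-hi against 86.5 CPM in CD11b-lo, the share of cells went the other way. A UMI was found after thinning in 1.29% (0.84 to 1.9) of CD11b-hi and 0.40% (0.23 to 0.63) of CD11b-lo macrophage-like cells.

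**Figure D2:**
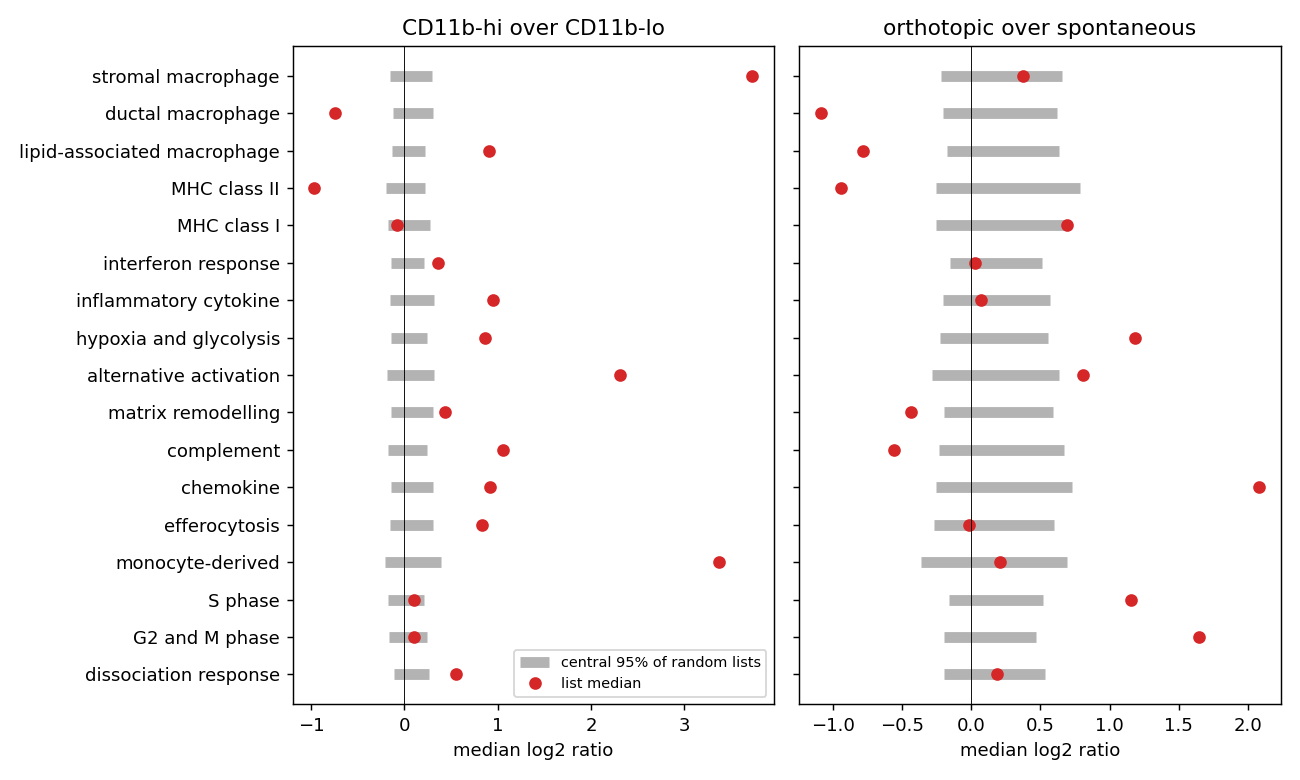
Median log2 ratio of each gene list in macrophage-like cells for both pairs, beside the central 95% of 10000 random lists matched on expression. The stromal list stands at 3.72 in CD11b-hi over CD11b-lo and at 0.38 in orthotopic over spontaneous.

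The spontaneous total sort was set between the fractions to describe where its macrophage-like cells lay. Of 465 genes at least 1 log2 unit apart between the fractions, 455 (97.8%) had a CPM in the total sort between those of the fractions. The sorts came from the same pool of mice, and the genes were picked for their distance between the fractions. A value in between was therefore largely fixed in advance and does not test whether the total sort was a mixture. The median position was 0.57 of the way from CD11b-lo to CD11b-hi. Folr2, for example, lay at 9.16 CPM in CD11b-lo, 120 CPM in the total sort and 205 CPM in CD11b-hi.

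The orthotopic and spontaneous total sorts compare tumours grown from injected cells with tumours that arose in place. Macrophage-like cells formed 46.7% of orthotopic cells (45.2 to 48.2) and 67.8% of spontaneous cells (65.7 to 69.8). Classical monocyte-like cells formed 27.2% and 12.7%, type 2 conventional dendritic cells (cDC2) 11.0% and 3.28%, and activated dendritic cells 6.56% and 0.441%. Epithelial-like cells, which the CD45 gate should remove, formed 0.046% and 3.48%. A pigment-lineage cluster with low Ptprc, described further below, formed 3.52% of orthotopic and 0% of spontaneous cells. The epithelial-like share alone therefore does not measure how many non-immune cells passed the sort. The macrophage-like share differed by -21.1 percentage points (-23.6 to -18.6), and by -37.9 at Leiden resolution 0.5, -31.7 at resolution 2.0 and at 5% mitochondrial UMIs, and -14.1 with each library clustered on its own. The classical monocyte-like shares were 29.8% and 0.147% at resolution 0.5, and 16.2% and 12.6% with each library clustered on its own, so their difference depended on the clustering in both libraries.

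Orthotopic macrophage-like cells were higher in chemokine and cell cycle genes and lower in Apoe and MHC class II genes. Cxcl9, a chemokine gene induced by interferon gamma, was 49.6-fold higher (44.4 to 55.5), and Ccl2, which attracts monocytes, was 10.3-fold higher (9.86 to 10.7). Apoe, a lipid transport protein, stood at 1655 CPM against 38308 CPM, 23.1-fold lower (22.9 to 23.4). Gdf3, a growth factor of the TGF-beta family, was 37.7-fold lower (33.7 to 42.3), and Cd74 was 4.72-fold lower (4.70 to 4.74). A Ccl2 UMI was found after thinning in 54.1% of orthotopic and 6.94% of spontaneous macrophage-like cells, beside 5.87% and 1.49% of cDC2-like cells. Without thinning, the macrophage shares of Ccl2 were 92.9% and 26.8%, at median depths of 12716.5 and 9314 UMIs, and cDC2-like cells had 7943 and 9575 UMIs. Orthotopic macrophage-like cells lay in clusters 17 (60.2%), 20 (28.1%) and 10 (10.9%), which held 0, 26 and 0 cells of the spontaneous total sort.

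The G2 and M phase list had 14 of 14 genes at least 1 log2 unit higher in orthotopic macrophage-like cells (median 1.65), among them Top2a (4.03-fold) and the proliferation marker Mki67 (4.02-fold). The S phase list had 9 of 14 higher (1.15), with Rrm1 at 3.81-fold. Cycling cluster 20 held 28.1% of orthotopic and 1.88% of spontaneous macrophage-like cells, and cycling cluster 5 held 0% and 8.82%. The summed counts do not separate a larger share of cycling cells from a higher level per cell. Hypoxia and glycolysis genes had 9 of 15 higher and 0 lower (1.18), among them Ndrg1 (15.8-fold) and the hexokinase gene Hk2 (3.67-fold). Chemokine genes had 7 of 12 higher and 2 lower (2.08), with Cxcl14 12.7-fold lower. In the alternative activation list 5 of 10 were higher and 1 lower (0.81), with Arg1 4.87-fold higher. The lower gene was Retnla (73.0 CPM against 557 CPM), whose share in spontaneous macrophage-like cells was 13.1% (11.35 to 14.98) beside 16.4% (8.49 to 27.5) of 67 cDC2-like cells, in which it stood at 101 CPM (78.2 to 129). In the MHC class I list 3 of 10 were higher (0.69), among them the peptide transporter gene Tap1 (2.21-fold).

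The ductal list had 7 of 12 genes lower and 0 higher, with a median of -1.09 (-1.14 to -1.04) below all random lists, among them the B cell coreceptor gene Cd72 (3.79-fold) and the tetraspanin gene Cd81 (2.82-fold). The lipid-associated list had 7 of 15 lower and 1 higher (-0.78), with Spp1 6.57-fold lower. A Spp1 UMI was found after thinning in 22.7% of orthotopic and 28.9% of spontaneous macrophage-like cells, and without thinning in 73.25% and 68.84%. The share of cells with Spp1 thus differed less than its summed level. MHC class II genes had 4 of 9 lower and 1 higher (-0.94), with H2-Ab1 3.07-fold lower. Complement genes had 4 of 10 lower and 1 higher (-0.56), with C1qa 2.27-fold lower, and matrix remodelling genes 6 of 15 lower and 2 higher (-0.43). The stromal list went both ways, with 4 of 13 higher, such as the mannose receptor gene Mrc1 (3.22-fold), and 3 lower, such as Ltc4s (4.56-fold). Its median was 0.38 (0.24 to 0.47), at percentile 69.6 of random lists, and ran from -0.105 over all called cells to 0.65 at Leiden resolution 0.5. Interferon response genes had 3 of 16 higher and 2 lower (0.03), with Cxcl10 4.32-fold higher and Ifit3 3.84-fold lower. The inflammatory cytokine (0.07), efferocytosis (-0.01), monocyte-derived (0.21) and dissociation response (0.18) lists had medians inside the random range, although the heat shock gene Hspa1b was 11.1-fold higher. The macrophage marker list itself was lower, at -0.87, and red cell markers at -2.84. The markers of classical monocytes (-0.41), non-classical monocytes (0.74), cDC1 (0.08), cDC2 (1.01) and neutrophils (-0.75) rested on 3 to 5 genes each. Median-of-ratios scaling shifted all ratios of this pair by -0.16, and relative to it the ductal median was -1.24 and the stromal median 0.22.

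**Figure D3:**
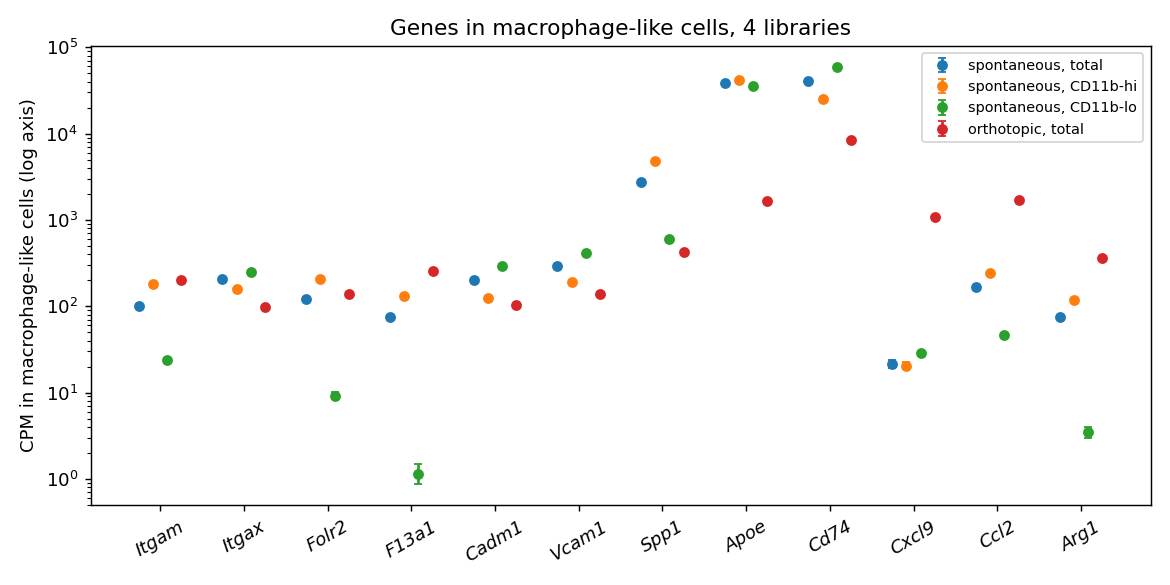
CPM of selected genes in macrophage-like cells of the 4 libraries on a log axis, with exact Poisson intervals that cover counting error only. Apoe stands at 38308 CPM in the spontaneous total sort and 1655 CPM in the orthotopic library.

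Other classes were compared where each library held at least 50 cells. In orthotopic cDC2-like cells (477 against 67), Cxcl9 was 80.9-fold higher (34.6 to 249). In orthotopic classical monocyte-like cells (1180 against 260), Cxcl9 was 37.1-fold higher, the angiogenic factor gene Vegfa 23.1-fold higher and Gdf3 60.8-fold lower, with free RNA not subtracted. Of these cells, 1175 orthotopic cells lay in cluster 9 and 258 spontaneous cells in cluster 4, and at Leiden resolution 0.5 only 0.147% of spontaneous cells stayed in the class. Of 16 hypoxia and glycolysis genes measured in these monocyte-like cells, 12 were at least 1 log2 unit higher and 0 lower, with a median of 1.52. Between the fractions, CD11b-hi cDC2-like cells (59 against 117) were 13.6-fold higher in the lectin gene Clec4b1 (8.94 to 21.4) and 16.6-fold lower in Plet1 (6.35 to 61.8). Free RNA was not subtracted here either. Clec4b1 was also among the 10 highest folds of unnamed cluster 16, which held 11.3% of CD11b-hi and 0.041% of CD11b-lo cells. Whether free RNA or doublets raised Clec4b1 in the cDC2-like cells was not tested.

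On GRCm38, Itgam (ENSMUSG00000030786) lies on chromosome 7 from 128062640 to 128118491, and Folr2 (ENSMUSG00000032725) on chromosome 7 from 101839988 to 101857194. F13a1 (ENSMUSG00000039109) lies on chromosome 13 from 36867178 to 37050244, Retnla (ENSMUSG00000061100) on chromosome 16 from 48842551 to 48844461, and Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050. Cd74 (ENSMUSG00000024610) lies on chromosome 18 from 60803848 to 60812652, and Apoe (ENSMUSG00000002985) on chromosome 7 from 19696109 to 19699188. Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 from 92321347 to 92328079, Ccl2 (ENSMUSG00000035385) on chromosome 11 from 82035571 to 82037453, and Gdf3 (ENSMUSG00000030117) on chromosome 6 from 122605403 to 122610087. Each span is that of the whole annotated gene, and 3' counting does not place a UMI in an exon.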

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

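The tests of Xist, Dct and keratin genes in pigment-lineage cells, and of UMIs and muscle genes in muscle RNA barcodes, were chosen after the result was seen. The lists of pigment and muscle genes were also written after the clusters were seen.

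A cluster of 153 cells with pigment-lineage genes formed 3.52% of orthotopic cells (2.995 to 4.12), although the sort required CD45, and its Ptprc stood at 15.5 CPM against 208 CPM in macrophage-like cells. Dct, a melanin synthesis enzyme gene, stood at 15958 CPM in these cells. Xist, expressed from the inactive X chromosome, stood at 4.33% (3.66 to 5.09) of its level in macrophage-like cells, where Malat1 was 7885 against 8075 CPM, which argues against pigment cells of the female hosts. Epcam, Krt8, Krt18 and Krt19 summed to 0.00655% (3 UMIs) of their level in epithelial-like cells, against keratin-expressing tumour cells. Dct in the other libraries reached at most 0.001005% of the orthotopic level (1 UMI). Mlana and Tyrp1 had 0 UMIs in the spontaneous libraries, against 9102 and 3984 in the orthotopic library, and Pmel had 6, 6 and 20 against 9803. The genes were picked from this cluster, but a source library would have to hold them. This argues against carry-over from the spontaneous libraries. A source outside the series and the identity of the injected line stay open.

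A cluster of 116 barcodes with macrophage and skeletal muscle RNA held 1.57% of the spontaneous total sort, 0.704% of CD11b-hi and 1.30% of CD11b-lo cells. Its median UMIs were 44.8% of those of spontaneous macrophage-like cells, which argues against pairs of whole cells. The muscle genes were 82.0-fold higher than in those cells, but they had been chosen from this cluster, so the test was void and free muscle RNA stays open. Malat1, a nuclear RNA, stood at 5.51% of their level, so fragments without nuclear RNA are a candidate explanation. No biological explanation was tested.

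Unnamed cluster 16, led by Retnla, Lyz1 and Cd2, held 5.69% of the spontaneous total sort, 11.3% of CD11b-hi and 0.392% of orthotopic cells. Unnamed cluster 18, led by the osteoclast genes Ctsk and Mmp9, held 0.735% of the spontaneous total sort and 0.335% of CD11b-hi cells. In the main clustering these clusters were not part of the macrophage-like class. They entered where all called cells were summed or the unnamed clusters nearest to macrophages were counted in. Runs that clustered anew could place their cells in named classes. With the highest doublet scores removed, 1.17% of CD11b-hi cells were unnamed and 78.8% macrophage-like. Each share lies above what a count of 0 allows.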

How the results depend on the processing

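The removal of the highest doublet scores and the counting in of unnamed clusters were chosen after seeing the data, as were macrophage markers without Apoe, which moved none of the 6 main values. Both share differences and the other 3 list medians kept their direction in every alternative run, and the stromal median of orthotopic over spontaneous kept it in all but 1. For each setting the values follow as share difference (percentage points), stromal and ductal median (log2). For the other values the cause was not tested. Keeping the 1 called doublet put the orthotopic macrophage-like share at 43.7% in place of 46.7%, so cluster borders moved with a single cell.

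In CD11b-hi over CD11b-lo, the share difference was -20.9 and the stromal median 3.815 at 1000 UMIs, and -26.6, 3.81 and -0.72 at 500 UMIs. They were -18.8 and 3.60 at 5% mitochondrial UMIs, -7.99, 3.53 and -0.87 at Leiden resolution 0.5, and -16.9, 3.65 and -0.78 at resolution 2.0. Separate clustering gave -15.3, 3.49 and -0.72, the highest doublet scores removed -10.7, 3.56 and -0.84, and the unnamed clusters counted in -12.2, 3.57 and -0.91. The stromal and ductal medians were 3.77 and -0.72 with free RNA subtracted, 4.27 and -0.92 as the mean of each cell's CPM, and 2.77 and -0.93 over all called cells. The ductal median was -0.78 under median-of-ratios scaling. The stromal median was 2.96 with no CPM minimum and 2.67 at 50 CPM, both from a changed set of genes, and 3.855 without cycling clusters.

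In orthotopic over spontaneous, the share difference was -28.2 at 500 UMIs and -31.7 at 5% mitochondrial UMIs, and the stromal median was 0.195 at 1000 UMIs. They were -37.9, 0.65 and -0.94 at Leiden resolution 0.5, and -31.7 and 0.63 at resolution 2.0. Separate clustering gave -14.1, 0.198 and -1.002, the highest doublet scores removed -30.4, 0.54 and -1.02, and the unnamed clusters counted in -28.7, 0.50 and -0.98. The stromal median was 0.52 with free RNA subtracted and 0.12 as the mean of each cell's CPM. Median-of-ratios scaling gave 0.22 and -1.24. Over all called cells the stromal median reversed to -0.105.

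Of 1170 values of 78 named genes in CD11b-hi over CD11b-lo, 8 reversed, and of 1230 values of 82 genes in the other pair, 4 reversed. Birc5 (0.21) was -0.061 at 5% mitochondrial UMIs, -0.017 and -0.051 at resolutions 0.5 and 2.0, -0.285 over all called cells and -0.106 with doublet scores removed. Ptprc (-0.14) was 0.038 and Slbp (-0.10) 0.031 with separate clustering, and Ptprc was 0.051 over all called cells. In the other pair, Plac8 (1.12) was -1.87 and Thbs1 (1.08) -0.37 at resolution 0.5, and Plac8 was -1.25 with free RNA subtracted and -0.86 with doublet scores removed. With 1 library per group, depth limits only the counting error, and the spread between animals was not measured.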

Other observations

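The tests of Apoe were chosen before their results were seen.

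In orthotopic macrophage-like cells, Cd274, which encodes the checkpoint ligand PD-L1, was 5.08-fold higher (4.33 to 5.99), and the interferon-induced GTPase genes Iigp1 and Gbp2 were 13.1-fold and 6.40-fold higher. Ptgs2, the inducible cyclooxygenase, was 7.34-fold higher. Tmem119, a gene known from microglia, was 11.1-fold lower, and Acp5, an acid phosphatase of osteoclasts and macrophages, was 12.9-fold lower. The nitric oxide synthase gene Nos2, named here after its values were seen, had a UMI after thinning in 2.71% of orthotopic macrophage-like cells and 0 of 1383 spontaneous ones (95% interval 0 to 0.27%), and without thinning in 11.6% and 0%. No cDC2-like cell of either library had one after thinning.

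Between 1000 UMIs and the minimum for a cell, the orthotopic library held 2523 barcodes with a median of 19.8% mitochondrial UMIs. The spontaneous total sort held 487 such barcodes with a median of 1.48%.

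Lower Apoe in orthotopic macrophage-like cells was weighed against free RNA, since Apoe stood at 43907 CPM in the free RNA of the spontaneous total sort and 1073 CPM in that of the orthotopic library. An Apoe UMI was found after thinning in 88.1% of spontaneous and 10.7% of orthotopic cDC2-like cells. After subtraction of free RNA the log2 ratio of Apoe was -4.44, which argues against free RNA as the whole cause. Among C1q-rich cells (9 orthotopic and 692 spontaneous) it was -2.17 (-2.26 to -2.08), between the bounds set in advance. This test could not decide whether fewer C1q-rich cells in the orthotopic library play a part. It rested on 9 orthotopic cells, and its interval covers counting error only. Apoe was also 22.7-fold lower in orthotopic cDC2-like cells and 52.0-fold lower in classical monocyte-like cells, with free RNA not subtracted. Tumour model, pool and library stay open, as they cannot be told apart here.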
